A study of Mus musculus with 2 samples.

How the data were processed

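Genomic DNA of 2 mouse haploid embryonic stem cell lines was examined, A129-2 on a 129Sv background and AOS-14 on a C57BL/6 background, with 1 library for each line. Per the labels' protocols, the cells came from AG-haploid embryos by cell sorting. The same protocols describe capture of about 100 Mb of mouse sequence with a methylation panel, bisulfite treatment and paired reads of 50 bp, while the series title names reduced representation bisulfite sequencing (RRBS), which cuts DNA at CCGG. The high share of CCGG among covered CpGs is given in the report, and the labels do not settle which method was used. Per the submitters' processing notes, BSMAP and the mouse build mm10 were used. The version of BSMAP, trimming, removal of duplicate reads and the treatment of reads with several positions are not given in the sources used here.

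Per the file headers, each library has 1 table with a row per CpG. The authors deposited the methylation level as a fraction from 0 to 1, and the read counts behind it as the number of reads and the number of methylated reads, both strands added. In each table the fraction equalled methylated reads over all reads within 0.0005, and the counts of the 2 strands added up to the total at all rows. Levels were recomputed from these deposited counts and are given here in percent. Starting positions in the tables count from 0 and were raised by 1.

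CpGs with at least 10 reads in both libraries were compared. Levels are means over CpGs unless said to be weighted by reads. The difference is A129-2 minus AOS-14 in percentage points. The methylated and unmethylated reads of the libraries were compared per CpG, per fixed window of 1 kb, per promoter and per imprinted region with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the units of one kind. Windows, promoters and regions needed at least 5 CpGs and were tested on summed reads. A difference was called at an adjusted p under 0.05 and a difference of mean levels of at least 25 points. Reads of 1 library are not independent cultures, so these tests and the exact 95% binomial intervals cover counting error only. At 10 reads such an interval runs from 18.7% to 81.3% for a level midway between none and full, and at 100 reads from 39.8% to 60.2%.

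On simulated reads at the real depths, the CpG test recovered 50.0% of 100 CpGs changed by 30 points and 77.0% of 100 changed by 40 points, with 11 false calls among 1030368 CpGs. The window test recovered 98.0% and 100.0%, with 0 false calls among 51142 windows. The analysis ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

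Gene positions came from the RefSeq table of GRCm38.p6, the assembly of mm10, which gives no strand. The design called for promoters by strand. In their place, a promoter window ran from 1 kb outside to 0.5 kb inside the gene end that held at least 2 times as many listed CpGs as the other end and at least 5. This resolved 16495 of 34614 genes, of which 13485 had enough CpGs, and genes whose promoter is poor in CpGs, or whose other end is rich in them, can be missed or misplaced. Imprinted intervals were placed at a set distance from the gene end nearest the middle of an interval fixed in advance. This was done where both overlapped (11 of 20 regions), otherwise the fixed interval itself was used (9 regions). The fixed intervals were written from general knowledge of mm10. The same holds for the bounds of the 5 gene clusters.

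The comparisons, the 14 gene lists, the alternatives and the rule for naming genes were set before the data were examined. The rule takes the 12 called promoters with the largest differences in each direction, leaving out predicted models named Gm or ending in Rik, called members of each list, the genes Pou5f1, Nanog, Dazl, Dnmt3l, Xist, H19 and Actb, and the 3 windows with the largest differences in each direction. Some results that this rule selects are not reported here. Of 324 list genes, 320 were found in the gene table. Random lists were drawn 10000 times, taking for each gene 1 of the 200 promoters nearest in mean level of the lines. An earlier matching in 10 groups of mean level was replaced after its result was seen, because the highest group spans a wide range of levels.

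Alternatives varied the minimum of reads, the size of difference, the number of CpGs, the weighting by reads, the window and promoter bounds, depth and chromosomes. In a further alternative strands were kept apart. Another left out CpGs under 5% in one line and at least 80% in the other whose neighbours differed little, as a strain variant could do. Only 25 CpGs had such levels and 6 of them were removed. A variant at a CpG of lower level would not be found this way, so this alternative cannot exclude strain variants. After the data were seen, CpGs outside CCGG and CpGs outside recurrent spacing patterns were added. A recurrent pattern is a run of 5 compared CpGs, with steps of at most 60 bp, whose steps recur at 40 or more places in either orientation. Dense CpG islands also repeat short steps by chance, so this set holds many unmethylated CpGs. Sequence variants between the strains were not analysed here.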

Results

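CpG methylation was measured in 2 mouse haploid embryonic stem cell lines, with 1 library per line. A129-2 carries a 129Sv background and AOS-14 a C57BL/6 background. Both are AG-haploid lines, taken here as androgenetic, which means that they hold a single chromosome set that came from sperm. Line and strain cannot be separated in this design, and no difference below has a replicate check. The tests compare the reads of these 2 libraries and not the strains.

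The A129-2 library listed 1699405 CpGs, of which 1065668 had at least 10 reads, from 153035567 read calls at CpGs. The AOS-14 library listed 1819756 CpGs, of which 1165015 had at least 10 reads, from 178315194 read calls. A total of 1030368 CpGs had at least 10 reads in both libraries and were compared, with a median of 79 reads in A129-2 and 97 in AOS-14. Across these CpGs, which are not independent replicates, the levels of the 2 lines had a Pearson r of 0.845. CpGs inside a CCGG motif made up 33.8% and 34.4% of the CpGs with at least 10 reads in A129-2 and AOS-14.

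Both haploid lines were methylated at a low level, and A129-2 was lower than AOS-14 in each class of sequence examined. The mean CpG level was 9.48% in A129-2 and 14.998% in AOS-14, a ratio of 0.632. CpGs at 50% methylation or more made up 1.02% of CpGs in A129-2 and 6.09% in AOS-14. Outside genes and promoter windows the mean level was 16.6% in A129-2 and 28.0% in AOS-14. Gene bodies stood at 10.9% and 17.1%, and promoter windows at 3.10% and 4.02%.

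The mean level was lower in A129-2 on 19 of 19 autosomes, with ratios of A129-2 to AOS-14 between 0.592 on chromosome 10 and 0.665 on chromosome 19. The X chromosome had means of 13.3% and 22.4%, a ratio of 0.593. Mitochondrial CpGs, of which 20 were compared, had means of 3.31% and 3.77%. Weighted by reads, the level was 9.71% in A129-2 (exact 95% interval 9.70 to 9.71) and 18.7% in AOS-14 (18.7 to 18.7), and the intervals cover counting error only. CpGs in CCGG motifs had means of 18.9% and 27.9%, and all other CpGs 4.74% and 8.49%, so the level differed with the motif while the order of the lines did not. The levels of the 2 strands of a CpG had a Pearson r of 0.443 in A129-2 and 0.641 in AOS-14 at CCGG. At other CpGs it was 0.802 and 0.899, so strands were less alike at CCGG, and the cause was not tested. The main results include CCGG. Results without it are given further below for means, CpGs, windows and promoters, and imprinted regions were not compared without it.

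**Figure D1:**
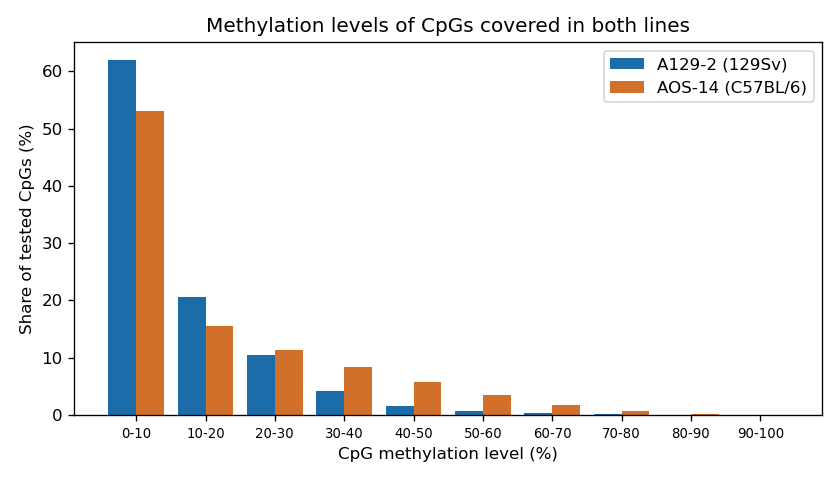
Share of the 1030368 compared CpGs (y axis, %) in each 10-point range of methylation level (x axis, %) for A129-2 (blue bars) and AOS-14 (orange bars), 1 library each. The lowest range holds 61.9% of CpGs in A129-2 and 53.1% in AOS-14, and from 20% upward each range holds a larger share of CpGs in AOS-14.

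Single CpGs and regions were compared to ask where the methylation of the 2 lines differs. Nearly all differences ran in 1 direction, with lower methylation in A129-2. Of 1030368 CpGs tested, 42053 were lower in A129-2 and 306 higher, by Fisher's exact test with Benjamini-Hochberg adjustment and a difference of at least 25 percentage points. Of 51142 windows of 1 kb, 2575 were lower in A129-2 and 7 higher. The windows called lower had a mean level of 20.4% in A129-2 and 52.8% in AOS-14.

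The 3 windows with the largest differences lay outside annotated genes. The window on chromosome 14 at 28620958 to 28620988, 28.7 kb from the gene model Gm35164, had a level of 13.9% in A129-2 (1236 reads) and 76.5% in AOS-14 (1496 reads) over 6 CpGs. On chromosome 5 at 52902026 to 52902496, 15.2 kb from Gm30241, 11 CpGs had levels of 8.66% and 68.9%. On chromosome 4 at 95509943 to 95509995, 22.1 kb from Gm12707, 5 CpGs had levels of 10.9% and 70.4%. In these 3 windows each CpG was lower in A129-2. Without CpGs in recurrent spacing patterns, 1642 windows were lower in place of 2575. Whether these 3 windows hold such patterns is not given here, so they may not be unique sequence.

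Among the 7 windows higher in A129-2, the 3 with the largest differences were on chromosomes 8, 13 and 3. The window on chromosome 8 at 3351533 to 3351627, inside Gm30369, had levels of 49.5% in A129-2 and 14.8% in AOS-14. The window on chromosome 13 at 119488228 to 119488554, inside Tmem267 and 3110070M22Rik, had levels of 50.2% and 16.6%. The window on chromosome 3 at 145978128 to 145978234, 4.82 kb from Gm35352, had levels of 39.1% and 6.82%. The first 2 of these had 0.158 and 0.0721 reads in A129-2 per read in AOS-14, outside the central 95% of windows (0.372 to 1.79). Chosen after their values were seen, the other windows include 1 inside Rbm20, a splicing regulator of heart muscle, at 32.3% in A129-2 and 6.62% in AOS-14 over 9 CpGs. There each CpG was higher in A129-2 and the read depths were alike, at 1325 and 1305 reads. Others lay inside Asap3, at 49.3% and 24.2%, and 8.58 kb from the olfactory receptor gene Olfr891, at 40.4% and 13.4%.

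The ratio of A129-2 to AOS-14 depended on the level in AOS-14. In windows under 10% methylation in AOS-14 the ratio of mean levels was 0.828, and it was 0.619 in windows of 20% to 30% and 0.504 in windows of 50% to 60%. It was 0.506 in windows of 60% to 70% and 0.599 in the 102 windows of 70% to 80%. Windows of at least 50% numbered 2752 in AOS-14 and 105 in A129-2, and 101 windows reached that level in both lines. The bins were set by AOS-14 alone, so counting error in AOS-14 adds to the gap in the highest bins.

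**Figure D2:**
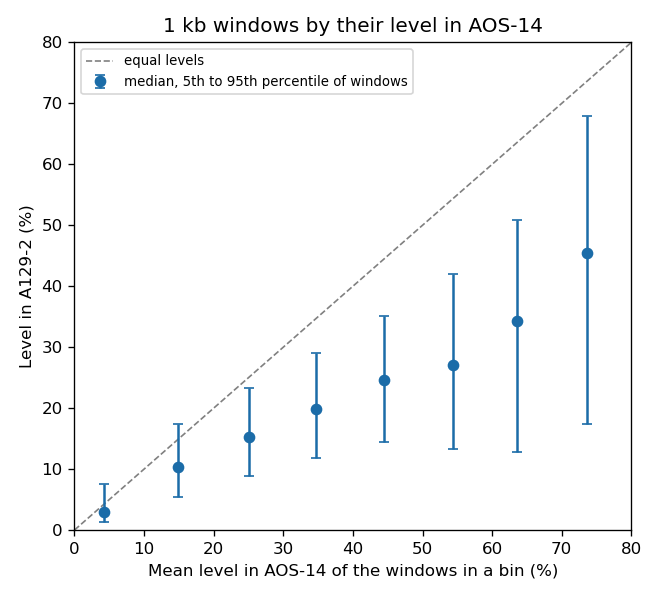
Methylation level in A129-2 (y axis, %) of 1 kb windows grouped by their level in AOS-14 in 10-point bins (x axis, mean level of the bin, %). Points are medians over windows, bars run from the 5th to the 95th percentile of windows, and the dashed line marks equal levels. The median in A129-2 is 15.2% where AOS-14 averages 25.05% and 27.2% where it averages 54.4%.

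Gene promoters showed few differences of this size. Of 13485 promoter windows with at least 5 compared CpGs, 37 were lower in A129-2 and 2 were higher, and most of these belong to predicted gene models. With no minimum on the size of the difference, 3849 promoters were lower and 93 higher at an adjusted p under 0.05 in Fisher's exact test. The promoters lower in A129-2 include those of Il1f9, a cytokine of the interleukin-1 family, and Vpreb1, a surrogate light chain of developing B cells.

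The Il1f9 promoter (chromosome 2, 24193604 to 24193641, 5 CpGs) had a level of 18.03% in A129-2 and 49.3% in AOS-14, from 1679 and 961 reads (adjusted p = 9.89e-60, Fisher's exact test). Sptbn5, a spectrin gene on chromosome 2, had 15.02% and 43.4%, Arl9 on chromosome 5 had 14.2% and 41.4%, and Vpreb1 on chromosome 16 had 13.6% and 40.1%. The noncoding gene LOC102640059 on chromosome 14 had 4.86% and 32.8%. In these 5 promoters all compared CpGs were lower in A129-2. The compared CpGs of Vpreb1 (16868666 to 16868842) all lie inside the gene, which starts at 16868401. Il1f9 kept too few CpGs to compare when CpGs in recurrent spacing patterns were left out. Outside CCGG, Il1f9, Sptbn5 and LOC102640059 kept too few CpGs to compare, while Arl9 differed by -25.0 points and Vpreb1 by -26.5 points.

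Tmem267, which encodes a membrane protein, was the named promoter higher in A129-2, at 49.1% against 17.8% in AOS-14 over 50 CpGs of chromosome 13 (119487251 to 119488554). Of these CpGs 35 were higher and 15 lower in A129-2, and the reads were uneven, with 2675 in A129-2 and 35556 in AOS-14. The gene model 3110070M22Rik lies over the same CpGs. With levels weighted by reads the difference was 15.9 points and no longer passed the criterion, and without CpGs in recurrent spacing patterns, a set chosen after seeing the data, it was -8.24 points.

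Dazl, a germ cell RNA-binding protein gene, had promoter levels of 14.8% in A129-2 and 16.0% in AOS-14 (adjusted p = 0.322, Fisher's exact test). Its difference depended on the promoter bounds, with -7.30 points for 2 kb outside the gene end and 0.856 points for 0.5 kb either side, neither of them called. The promoter window of H19, a maternally expressed noncoding RNA, had 6.86% and 8.79% (adjusted p = 0.507, exact test). Pou5f1 had too few compared CpGs. For Nanog, Dnmt3l, Xist and Actb the gene end that holds the promoter was not resolved from CpG density, and no value is given.

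Imprinted regions were examined because a genome from sperm alone should lack methylation that is set in the egg and carry methylation that is set in sperm. The 15 regions methylated on the maternal allele were low in both lines, with a median of 3.83% in A129-2 (range 0 to 14.5) and 5.39% in AOS-14 (0.510 to 8.15). None of them passed the criterion. The Dlk1-Meg3 intergenic region, which is methylated on the paternal allele, had 8.53% in A129-2 and 30.7% in AOS-14. Neither line was near full methylation at the compared CpGs, which cover only a part of that region.

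Among maternally methylated regions, Snrpn had levels of 5.38% in A129-2 and 5.39% in AOS-14, Peg3 5.82% and 4.89%, Grb10 3.83% and 3.70%, Impact 2.72% and 4.90%, Plagl1 3.64% and 5.68%, and Zrsr1 3.45% and 4.09%. Peg10 had 1.71% and 3.18%, Nnat 5.90% and 8.15%, Peg13 6.52% and 7.39%, exon 1A of Gnas 5.66% and 6.55%, and the Nespas-Gnasxl region 6.57% and 5.65%. At Airn-Igf2r, 0 of 83 reads were methylated in A129-2, which allows a level of up to 4.35% (exact 95% interval), and 1 of 144 in AOS-14. At an adjusted p under 0.05 but under 25 points, 3 regions differed, namely Gpr1-Zdbf2 at 3.21% and 7.71%, Mcts2 at 2.54% and 5.59%, and the region of the Inpp5f variant 2 transcript at 14.5% and 4.97%. The last was higher in A129-2 at 7 of 7 CpGs, from 128 reads in A129-2 and 413 in AOS-14 (adjusted p = 9.69e-05, Fisher's exact test).

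The Dlk1-Meg3 region was measured at 8 CpGs of chromosome 12 between 109525712 and 109526736, overlapping the gene model Gm34081. The interval searched ran from 109524996 to 109530996, so most of it held no compared CpG. All 8 CpGs were lower in A129-2, and the region differed by -22.2 points (adjusted p = 1.45e-66, Fisher's exact test; 1662 and 1669 reads), short of the 25-point criterion. With the interval fixed in advance in place of the one placed from an annotated gene end, the difference was -28.4 points and passed it. Its level in A129-2 lay at percentile 1.68 of the 7075 windows within 5 points of its level in AOS-14. The other regions methylated in sperm had too few CpGs, with 1 CpG at H19 and 3 at Rasgrf1, as did Mest with 2 and Kcnq1ot1 with 0.

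**Figure D3:**
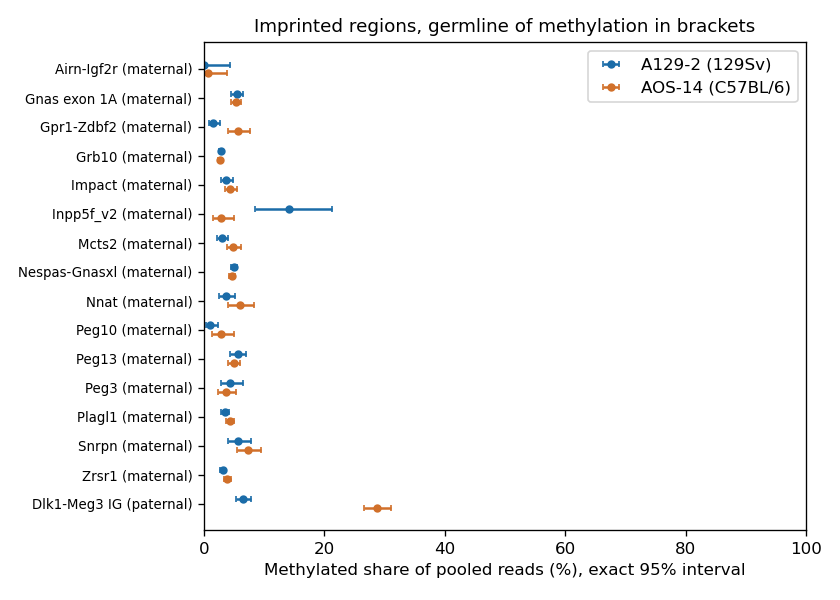
Methylated share of pooled reads (x axis, %) at 16 imprinted regions, with the parental allele that is normally methylated in brackets, in A129-2 (blue) and AOS-14 (orange). Bars are exact 95% binomial intervals, which cover counting error only. The 15 maternally methylated regions lie at or under 14.1% in both lines, and the Dlk1-Meg3 region stands at 6.50% in A129-2 and 28.8% in AOS-14.

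Gene groups of pluripotency, lineage, germline and methylation control were examined at their promoters. No promoter passed the criterion among 165 tested members of 14 lists, nor did any when the test was adjusted over the list alone. Only 4 of the 165 (Dpep3, Hoxd4, Sycp3 and Tex101) had at least 25% methylation in AOS-14, so for the others a call of lower methylation in A129-2 was out of reach. Pluripotency and lineage promoters had low median levels in both lines. Germline gene promoters had the highest median levels of the lists, at 10.1% in A129-2 and 12.1% in AOS-14.

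The 13 naive pluripotency promoters had medians of 2.56% in A129-2 and 3.46% in AOS-14, with 1.95% and 3.22% at Klf4 and 0.858% and 1.34% at Sox2. Of these, 13 of 13 were lower in A129-2, and 4 of them at an adjusted p under 0.05. Over all 13485 tested promoters 84.0% were lower, and 3849 at an adjusted p under 0.05, so these counts do not set the list apart. The median difference of the list lay at percentile 31.6 of matched random lists. Levels this low are near those of mitochondrial CpGs, at 3.31% in A129-2 and 4.52% in AOS-14 weighted by reads. The 14 promoters of the DNA methylation machinery had medians of 2.45% and 3.23%, among them the methyltransferase gene Dnmt3b at 2.02% and 2.36% and the dioxygenase gene Tet2 at 2.55% and 4.99%. The 17 neuroectoderm promoters had medians of 3.22% and 4.49%, the 12 mesoderm promoters 3.36% and 4.82%, the 7 primitive endoderm promoters 6.94% and 5.26%, and the 9 trophoblast promoters 3.90% and 5.81%. The largest gaps in these lists were at the heart and limb gene Tbx5, at 9.52% and 15.6%, and the keratin gene Krt8, at 11.95% and 19.4%. For primitive endoderm the list medians and the median difference of -0.915 points differ in sign.

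The 8 fibroblast markers had medians of 3.36% and 3.97%, and the 11 housekeeping promoters 2.91% and 2.96%. Whether the fibroblast promoters would differ in feeder cells is not known from these data, so their levels do not show whether feeder DNA was present. The single tested promoter of the 2-cell-state list, Eif1a, had 2.36% and 2.80%. In the X inactivation centre list, Rlim had 1.52% and 1.42% and Jpx 3.75% and 3.41%. The 13 promoters of maternally methylated imprinted genes had medians of 3.42% and 5.68%, and some of these windows lie outside the methylated regions. The median difference of this list, -2.25 points, lay at percentile 0.190 of 10000 random lists matched on mean level, while the median difference of the 15 maternally methylated regions was -0.867 points. The list's largest gaps were at gene ends outside those regions, with 11.7% in A129-2 and 21.8% in AOS-14 at Inpp5f and 2.57% and 7.69% at Gnas.

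The 23 germline promoters included 3 with at least 20% in AOS-14. These were the testis genes Dpep3, at 35.5% in A129-2 and 55.3% in AOS-14, and Tex101, at 21.4% and 41.2%, and the meiotic chromosome axis gene Sycp3, at 17.5% and 29.1%. The synapsis gene Sycp1 had 12.8% and 12.1%, and the germ cell helicase gene Ddx4 had 6.79% and 5.43%. At an adjusted p under 0.05, 9 of the 23 were lower in A129-2 and 2 higher, and the mean difference was -3.22 points. Over all 13485 tested promoters 3849 were lower and 93 higher. The median difference of the list was -1.17 points, at percentile 99.2 of matched random lists and 97.9 when they were also matched on the number of CpGs. These percentiles describe the 2 libraries and are not tests of the lines.

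Hox and protocadherin genes lie in dense clusters and were examined as regions. Levels in the 4 Hox clusters and the protocadherin cluster were low in both lines, and 0 of their 205 windows were called. Only 8 of these windows had at least 25% methylation in AOS-14, so the criterion could hardly be met there and the count is not set against other windows. Mean levels were 4.13% in A129-2 and 5.65% in AOS-14 for Hoxa, 5.95% and 7.95% for Hoxb, 4.92% and 7.05% for Hoxc, 5.01% and 6.42% for Hoxd, and 8.46% and 11.8% for the protocadherins.

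At promoters, the 26 tested Hox genes had median levels of 3.27% and 4.56%, and 6 were lower in A129-2 at an adjusted p under 0.05. Over all tested promoters 3849 of 13485 were, and the median difference of the Hox list lay at percentile 29 of matched random lists. The window of Hoxc12, a posterior patterning gene, had 3.32% and 11.3% (adjusted p = 9.61e-09, Fisher's exact test). It lies at the opposite gene end from the windows of the other tested Hoxc genes, so it may not be the promoter. Hoxa3, Hoxb2 and Hoxd11 stood apart from the other tested genes of their clusters in the same way. The 11 tested promoters of clustered protocadherins, neuronal adhesion genes, had medians of 3.32% and 4.54%, and none differed at an adjusted p under 0.05. Their median difference of -1.66 points lay at percentile 1.03 of matched random lists, and at 4.55 when they were also matched on the number of CpGs.

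Sex chromosomes were read as a check of library content. The X chromosome held 3.03% of CpGs with at least 10 reads in A129-2 and 3.02% in AOS-14. The Y chromosome held 0.180% and 0.199%. Around the ends of Kdm5d, Eif2s3y, Uty, Ddx3y and Usp9y, single-copy genes of the Y chromosome, 35 reads were found in A129-2 and 21 in AOS-14, and 1 and 0 CpGs had at least 10 reads. Around their X partners Kdm5c, Eif2s3x, Kdm6a, Ddx3x and Usp9x, 28650 and 30481 reads were found at 249 and 267 such CpGs. With so few reads at these Y genes, the Y share above is not evidence of a Y chromosome in either line. How well these genes are covered when a Y is present is not known from these data, and the source of the other Y reads was not tested.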

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

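All tests in this part were chosen after the result was seen.

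Some CpGs had reads in 1 library and none in the other, and so entered no comparison. In AOS-14, 20798 of 1044861 CpGs with at least 20 reads were absent from the A129-2 table, which is 1.99% and a median of 68 reads. In A129-2, 3287 of 931905 such CpGs were absent from AOS-14, or 0.353%. Runs of 20 or more such CpGs numbered 9 in AOS-14 and 2 in A129-2. They include 34 CpGs at Plxnd1, a semaphorin receptor gene (chromosome 6, 115994672 to 115994854), with a level of 0.995% in AOS-14, and 23 at the ion channel gene Trpv4 (chromosome 5, 114658386 to 114658552), at 1.98%. Both runs present in A129-2 lie at Elovl5, a fatty acid elongase gene on chromosome 9. No explanation for these was tested.

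For the lower methylation of A129-2 across the genome, a candidate explanation is incomplete bisulfite conversion in AOS-14, which would lift unmethylated DNA by about as much as other DNA, but its promoter windows averaged 4.02%, against a genome-wide gap of -5.52 points and larger gaps in called windows. Biparental cells with intact imprints in the AOS-14 library, which the cell sorting named in the labels would remove if it selected haploid cells, would carry methylated maternal alleles, but the median of maternally methylated regions there was 5.39%, too low for a share that would explain the called windows. The median difference of these regions was -0.867 points, and a share too small to explain the pattern was not tested. Cytosines added by end repair at CCGG sites would leave other CpGs alike, but outside CCGG the ratio of A129-2 to AOS-14 was 0.559. Strain, line, passage and culture go together with the library and stay open, so no biological explanation could be set apart.

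The region between Dlk1 and Meg3 was lower in A129-2 than most windows of like level in AOS-14, and a candidate explanation is chance within the loss shared by such windows. With any 1 CpG left out, its level in A129-2 lay at percentile 0.853 to 3.19 of those windows, which is low. A bound of percentile 5 for excluding this explanation was set first and replaced by 1 after the value was seen, because 5% of such windows lie under percentile 5 themselves, so the explanation is left open. All 8 CpGs were lower in A129-2, by -6.27 to -35.3 points, so the difference was not confined to a single CpG. However, 62.4% of all tested CpGs and 88.3% of all tested windows were lower too. This count therefore cannot exclude sequence variants at some of the CpGs, which stay open. A loss of the paternal imprint was not tested in either line, for want of other regions of that kind with enough CpGs. AOS-14, at 30.7%, was itself far from full methylation at the compared CpGs. The other regions went opposite ways, with 17.5% in A129-2 and 10.9% in AOS-14 at 1 CpG of H19, and 14.6% and 25.8% at 3 CpGs of Rasgrf1.

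A recurrent spacing pattern of 5 CpGs had steps of 4, 5, 7 and 7 bp. It was the most frequent of 109 patterns with at least 20% methylation in AOS-14. Its 499 copies were placed on 21 chromosomes of the mouse build, with 17.8% in A129-2 and 57.6% in AOS-14. Of its copies 94.8% lay under the median A129-2 level of non-recurrent runs within 5 points of their own AOS-14 level. Most copies were thus lower than such runs, and the mean of the pattern lay at percentile 7.72 of them. The copies may share reads and are not independent. The share of copies therefore cannot decide whether the loss shared by such runs is the whole cause. Non-recurrent runs within 5 points of the mean AOS-14 level of the pattern averaged 31.2% in A129-2. Cytosines added at CCGG are argued against by the ratio of 0.276 at its other CpGs. Placement of reads among copies of a repeated sequence stays open: reads at the copies, relative to all compared CpGs, had a ratio between libraries of 1.02, but the tables do not record how such reads were placed. A repeat family that may be less methylated in A129-2 is the biological alternative, and the sequence of the copies was not analysed here.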

How the results depend on the processing

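The alternatives with CpGs outside CCGG and without recurrent spacing patterns were chosen after the data were seen; the others were planned. A129-2 had the lower mean in each alternative that gave means, and calls of lower methylation outnumbered the opposite wherever CpGs, windows or promoters were called. Of the alternative values of the main results, 75 stayed within the counting interval, the spread over imprinted regions or 1.5 times the count, and the other 50 follow; the cause was not tested except where fewer or more CpGs, windows or promoters enter by construction. Counts are given as lower, then higher, in A129-2. No paired analysis was possible because each line has 1 library.

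With at least 5 reads the means were 9.71% in A129-2 and 15.3% in AOS-14 (ratio 0.635), with 530 CpGs and 16 windows higher. With 20 reads they were 9.30% and 14.8% (0.628), with 4 windows higher. Weighted by reads they were 9.71% and 18.7% (0.520), with 0 promoters higher. Outside CCGG they were 4.74% and 8.49% (0.559), with 22852 and 189 CpGs, 1321 and 3 windows, and 15 promoters lower. Without recurrent patterns they were 10.99% and 17.3% (0.637), with 1642 windows lower and 0 promoters higher, and Tmem267 reversed to -8.24 points.

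At a difference of 10 points the calls were 121135 and 1049 CpGs, 14977 and 55 windows, and 376 promoters lower. At 50 points they were 3318 and 70 CpGs, 60 and 0 windows, and 2 and 0 promoters. With reads thinned to equal depth 188 CpGs were higher. With at least 3 CpGs, 4854 windows and 56 promoters were lower, and with at least 10 CpGs, 666 and 1 windows and 10 promoters lower. Promoters reaching 2 kb outside the gene end gave 1 higher, and windows shifted by 0.5 kb gave 4 higher. Fixed intervals gave 1 called imprinted region. Over all CpGs listed, X held 3.27% and 3.22% and Y 0.381% and 0.350% in A129-2 and AOS-14.

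At the depth of these libraries, the simulated recovery was lower for single CpGs than for windows. The 5 named lower promoters lost their call only at 50 points, among alternatives that left them enough CpGs.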

Other observations

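All tests in this part were chosen after the result was seen.

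Repeated CpG arrangements were examined as a group. Among 109 recurrent spacing patterns with at least 20% methylation in AOS-14, 109 had a lower mean in A129-2, with ratios of A129-2 to AOS-14 from 0.240 to 0.813 and a median of 0.512, against 0.575 in runs whose spacing does not recur, at the same minimum level. Some patterns share steps and can be shifted or reversed readings of the same copies, so their counts are not of separate items. In 26 patterns the ratio was under 0.4. Set against runs of CpGs whose spacing does not recur and whose AOS-14 level is within 5 points, 77 patterns had a lower mean in A129-2 and 32 a higher one, with a median difference of -1.96 points and a range from -16.4 to 7.03. The pattern with steps of 7, 5, 4 and 29 bp had 476 copies with 18.8% in A129-2 and 59.6% in AOS-14, lower than like runs by a difference of -13.6 points. Its first steps are those of the most frequent pattern read backwards, so they can share copies. The pattern with steps of 8, 5, 5 and 31 bp had 96 copies with 28.5% and 39.1%, above like runs by 7.03 points.

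A hypothesis that CpG-dense windows keep more of their methylation in A129-2 was set against windows of 20% to 50% in AOS-14. The ratio of A129-2 to AOS-14 was 0.588 in windows of 5 to 9 compared CpGs. It was 0.573 in windows of 10 to 19 and 0.528 in the 195 windows of 20 to 65. Windows with more compared CpGs thus did not keep more of their methylation. The number of compared CpGs depends on coverage and is not the CpG density of the sequence. The share of CCGG in these windows was not examined either, so the hypothesis is not settled.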
